A study of Mus musculus with 6 samples.

How the data were processed

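Total RNA from growth plate chondrocytes of the mouse hindlimb was measured on Affymetrix arrays, with 3 control and 3 Lkb1 mutant samples at day 30 after birth. Per the labels' protocols, RNA was isolated with a silica column kit, and 300 ng was turned into biotin-labelled cDNA with a whole-transcript kit; the mice had a mixed FVB, 129S6 and C57 background. The only values used are the intensities the authors deposited in the series' value table, with 35512 probe sets on each of the 6 arrays. How the authors summarised the probes into these intensities and normalised them between arrays is not given in the sources used here. The deposited intensities are on a linear scale, from 0.74 to 9001, with array medians of 82.4 to 90.5, so scale and direction are clear from the values while the summary method and the background correction stay unknown. Each sample's group and replicate number came from its title. All value columns matched a sample, and 0 columns were left out.

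Genes were named through the platform annotation, updated by gene number to the RefSeq gene table of assembly GRCm38.p6, from which no coordinates were taken; no genome build is named for the arrays, and none was used here. Of the 35512 probe sets, 21789 were annotated to 1 gene, 1621 to several and 12102 were not listed. By gene number 21698 of the 1-gene probe sets matched, and the other 91 kept their annotated symbol. Only probe sets of 1 gene entered the main test. The intensities were transformed to log2(intensity + 1) without further normalisation. Probe sets with a mean in the lowest 25% of all probe sets (below 5.56, an intensity of 46.2) were left out. Of several probe sets of a gene the one with the highest mean over all arrays was kept, which left 17020 genes.

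Mutant and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a call at an adjusted p of 0.05. Every adjusted p of a gene is from this test. The design, the alternatives, 33 gene lists with 416 genes and the rule for the genes named in the text were fixed before the data were examined. The rule names Stk11, the 12 genes with the largest change in each direction among called genes whose groups do not overlap, and up to 4 called members of each list with the largest change (where none is called, the 2 with the smallest p as values); it gave 109 genes. Col2a1, Acan, Col10a1, Ihh, Gli1, Ptch1, Hhip, Ldha, Pgk1, Prkaa1 and Prkaa2 are members of these lists that were singled out after their values were seen. Of the list genes, 381 had a probe set of 1 gene and 374 were tested. Each list with at least 4 measured members was tested with camera at its preset correlation of 0.01, adjusted over the 32 lists tested; camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes tested. The list of Y-linked genes served only to compare the sex of the mice. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used for single genes.

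The test was checked on simulated arrays with the measured means and spreads, 5 runs of 200 changed genes among 17020. It called 22.4% of genes changed by 0.5 on the log2 scale, 76.7% of those changed by 1 and 97.6% of those changed by 2, and 31 of 84100 unchanged genes. A simulated list shifted by 0.5 was called in 5 of 5 runs, and 0 of 155 tests of other lists were called. The simulated genes were independent of each other, so this check says nothing on lists whose genes move together. Both groups were drawn with 1 pooled spread per gene, so the rates hold for equal spreads. They also hold only for 200 changed genes. The measured fit called 2496 genes, and the adjustment is less strict where more genes differ. Measured genes such as Mki67 varied more among the controls (SD 0.79) than among the mutants (SD 0.08). The alternatives were quantile normalisation, median centring, no filter or a filter at the median, the mean of a gene's probe sets, an intensity trend, array weights, the replicate number as a block, a pseudocount of 16, a threshold on size and leaving out each array. Settings added after the data were seen were a fit without control replicates 2 and 3 and a fit with the mean of 25 erythroid, neutrophil and B lymphoid genes as a covariate. That mean separates the groups completely, so the covariate fit extends the trend among the arrays of each group over a range that holds no array.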

Results

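Gene expression was measured in mouse growth plate chondrocytes, the cartilage cells that lengthen bones, taken from the femurs and tibiae of animals at postnatal day 30. Each sample was hybridised to its own single-channel Affymetrix array, and the samples form 2 groups of 3: control mice and mice with a conditional mutation of Lkb1. Lkb1 is the older name of Stk11, which encodes a kinase that activates AMPK and a family of related kinases. The labels call the replicates biological but do not say that they came from separate animals or litters, so the p-values measure the spread between these samples. The median intensity per array lay between 82.4 and 90.5, and the 3 arrays per group limit the precision of every value. Values are given as log2(intensity + 1), which understates a fold change of a dim gene slightly. Background signal, described below, also limits such a fold change. Across all 35512 probe sets, arrays of the same group correlated at r = 0.960 to 0.972 for the controls and 0.979 to 0.984 for the mutants. Arrays of different groups correlated at 0.940 to 0.965. Probe sets are not independent replicates, and these coefficients only describe the arrays.

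Stk11 (probe set 10364683) was lower in every mutant array than in any control array. Its level was 8.68, 9.08 and 9.67 in control replicates 1, 2 and 3, and 7.39, 7.51 and 7.52 in mutant replicates 1, 2 and 3. The difference was -1.67 on the log2 scale (SE 0.22, n = 3 per group), 3.18-fold lower in the mutants, with a limma adjusted p of 0.00387. Where the probes of this set lie relative to the deleted part of the gene was not analysed here, and probes outside it would not check the genotype. Among the controls, the array with the highest Stk11 level also had the highest level of bone marrow markers. The mean of 25 erythroid, neutrophil and B lymphoid genes was 8.62, 9.27 and 9.94 in control replicates 1, 2 and 3, against 6.27, 6.23 and 5.98 in the mutants. The Stk11 difference was -1.21 without control replicates 2 and 3. That fit leaves a single control and holds no spread between controls, so no p of it is given. With the marrow level as a covariate the Stk11 difference was 0.48 (adjusted p = 0.561). Both settings were chosen after the data were seen. With other normalisations, filters, variance models or 1 array left out the Stk11 difference lay between -1.90 and -1.41, with adjusted p from 6.68e-06 to 0.0223. The lowest of these is from array weights, a fit that did not converge, and the next lowest was 0.000799 without control replicate 1.

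The comparison of mutant with control samples asks which transcripts differ in growth plates that carry the Lkb1 mutation. Of the gene lists tested, that of fibrous connective tissue and tendon had the highest median, and those of erythroid cells and neutrophils had the lowest. Of 17020 genes tested, 2496 passed an adjusted p of 0.05, with 1335 higher and 1161 lower in the mutants. Among them, 723 differed by at least 1 on the log2 scale, 269 higher and 454 lower. The groups did not overlap for 6249 genes, or 36.7%, where chance gives 10% with 3 against 3 arrays. The number of calls fell to 1329 without control replicate 2, to 1198, 1185 and 936 without mutant replicates 1, 2 and 3, and to 2 with the marrow level as a covariate. The 1035 probe sets of olfactory receptor genes serve here as a background, with medians of 5.17 to 5.49 and 95% points of 6.40 to 6.73 per array. Of the 109 genes chosen by rule, 17 that were higher in the mutants did not exceed the 95% point in all controls, and 23 that were lower did not exceed it in all mutants, so the size and the rank of these differences are limited by the background. The 17 are Tnn, Otor, Ptn, Sfrp2, Saa2, Atp6v0d2, Mrc1, Esam, Kdr, Myl1, Actn3, Fabp4, Lpl, Tnmd, Car9, Adamts4 and Ifit3. The 23 are the erythroid, neutrophil and B lymphoid genes named below and Ctse, Ltf, Car2, S100a8, Car1, Phex, Calcr, Cdc6, Slc7a11, Stradb and Rsad2. In neither group did all arrays exceed it for Kdr, Myl1, Car9, Calcr and Klf1.

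The 12 largest measured increases were in Tnn, Pi15, Otor, Postn, Ptn, Aspn, Col8a1, Sfrp2, Prss35, Thbs2, Cdh11 and Saa2; Otor, Ptn and Saa2 were at background in all controls, and Tnn and Sfrp2 in 2 of 3. Tnn, which encodes the matrix glycoprotein tenascin-W, rose from 6.53 ± 0.49 to 10.51 ± 0.25 (SD, n = 3 each), with an adjusted p of 0.00026. Postn, which encodes the matrix protein periostin, rose by 3.51 (SE 0.41, adjusted p = 0.00223), and Aspn, which encodes the small leucine-rich proteoglycan asporin, by 3.17 (SE 0.30, adjusted p = 0.00113). Sfrp2, a secreted modulator of Wnt signalling, Ptn, which encodes the growth factor pleiotrophin, and Otor, a secreted protein related to the cartilage protein MIA, were above background in all mutants. Cdh11, a cadherin of mesenchymal cells, rose 6.55-fold, and Col8a1, a chain of a short-chain collagen, 7.80-fold. Saa2, an acute phase gene, had the widest spread among the mutants of these genes (SD 1.14), and its adjusted p was 0.0602 without mutant replicate 3. Of these 12 genes, all but Pi15, Otor, Col8a1 and Saa2 fell steadily across control replicates 1, 2 and 3, in which the marrow markers rose. Postn was at 9.05, 8.33 and 7.17 there. With the marrow level as a covariate the Postn difference was -0.78, and the others of the 12 kept their sign. Most markers of fibrous tissue and endothelium were also higher in the mutants. Most or all markers of erythroid, neutrophil and B lymphoid cells were lower. Camera called none of these lists with an estimated correlation.

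Transcripts of 3 blood lineages of the bone marrow were higher in the controls, at levels that differed between the control arrays. In all mutants, 0 of 5 erythroid, 4 of 11 neutrophil and 1 of 9 B lymphoid genes exceeded the background, against 4, 11 and 7 in all controls. All 5 measured erythroid genes fell, and all 5 also passed when adjusted over the list alone. Slc4a1, which encodes the red cell anion exchanger, fell by 4.38 (SE 0.47, adjusted p = 0.00157), and Alas2, the erythroid enzyme that starts haem synthesis, fell by 4.09 (SE 0.31). Rhag fell by 4.36, and Klf1, an erythroid transcription factor, fell by 3.06, with an adjusted p of 0.081 without mutant replicate 3. The list was called by camera (adjusted p = 5.16e-06), with an adjusted p of 0.34 with an estimated correlation. Of 11 neutrophil and granulocyte precursor genes, 10 fell, and 11 when adjusted over the list alone. Mpo, the myeloperoxidase gene, had the largest measured decrease, from 10.59 ± 0.80 to 5.30 ± 0.20 (SD, n = 3 each), which is background, with an adjusted p of 0.000337. Elane (neutrophil elastase, -4.85), S100a9 (-4.29) and Mmp8 (-4.24) fell as well. The camera adjusted p of this list was 1.18e-13, and its adjusted p was 0.295 with an estimated correlation. The erythroid, neutrophil and B lymphoid medians of -4.09, -4.18 and -1.66 were 2.13, -0.97 and 0.20 with the marrow level, which is their own mean, as a covariate. Of 9 B lymphoid genes, 7 fell, and 7 when adjusted over the list alone, with a camera adjusted p of 5.91e-08 and an adjusted p of 0.332 with an estimated correlation. Decreases were found in Cd79b (-3.57) and Cd79a (-3.53), which encode the signalling chains of the B cell receptor, and in Igll1 (-3.23) and Vpreb3 (-2.15). The rest of the 12 largest decreases were in Ctse, Ltf, Car2, S100a8 and Car1. None of the genes named in this paragraph exceeded the background in all mutants, so their decreases are limited by it.

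**Figure D1:**
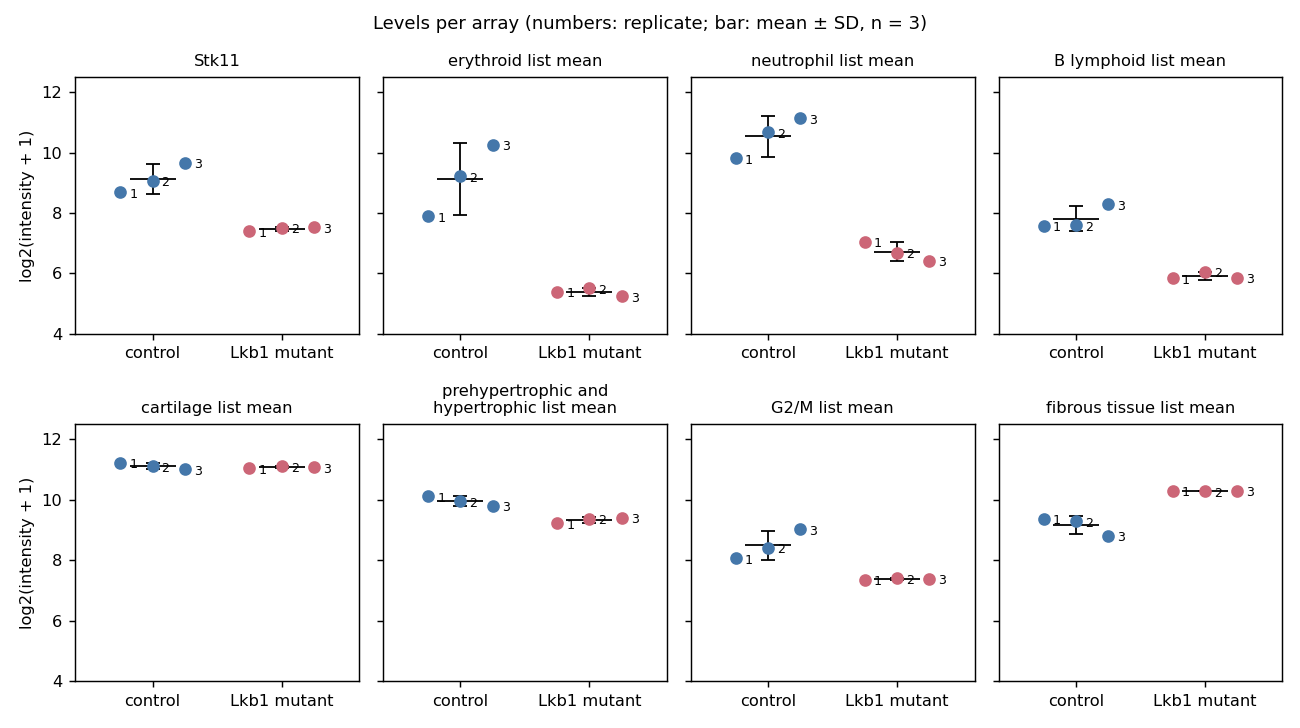
Level per array, as log2(intensity + 1) on the vertical axis, of Stk11 and of the means of 7 gene lists in the control (blue) and Lkb1 mutant (red) samples; numbers are replicates, and black bars show the mean and SD of the 3 arrays. Stk11 lies between 8.68 and 9.67 in the controls and between 7.39 and 7.52 in the mutants, the erythroid mean lies between 7.89 and 10.26 in the controls and between 5.25 and 5.51 in the mutants, and the cartilage means of the groups overlap.

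Genes of cartilage matrix and chondrocyte identity differed little in the fit of all arrays, and genes of the prehypertrophic and hypertrophic zone, where chondrocytes leave the cycle and enlarge, were lower in the mutants. Of 20 cartilage genes, 1 rose and 1 fell, likewise 1 and 1 when adjusted over the list alone, and the list was not called (median -0.08, adjusted p = 0.0917). It was called lower without control replicate 3 (median -0.13, adjusted p = 0.0094) and with the marrow level as a covariate (-0.53, adjusted p = 7.63e-05). Its median was -0.16 without control replicates 2 and 3. Col2a1 and Acan, the genes of the main collagen and proteoglycan of cartilage, differed by 0.04 and -0.03, with adjusted p of 0.776 and 0.862. Matn1, a cartilage matrilin, rose by 1.28 (SE 0.29, adjusted p = 0.0248), and Sox6, a transcription factor of chondrocytes, fell by 0.38 (SE 0.09, adjusted p = 0.0282). Both calls ended without control replicate 2 and without each of the mutant replicates, with adjusted p of up to 0.0908 for Matn1 and 0.123 for Sox6. Of 11 prehypertrophic and hypertrophic genes, 6 fell and none rose, and 9 fell when adjusted over the list alone. Pth1r, the parathyroid hormone receptor, fell from 10.67 ± 0.10 to 9.55 ± 0.09 (SD, n = 3 each), 2.18-fold (adjusted p = 0.00066). Foxa2, a transcription factor of hypertrophic chondrocytes, fell by 1.29 (SE 0.19, adjusted p = 0.00498), and Bmp6 (-0.89) and Panx3 (-0.87) fell too. Col10a1, the collagen of hypertrophic cartilage, fell by 0.50 (adjusted p = 0.0114), while Ihh differed by -0.15 (adjusted p = 0.453). The camera adjusted p of this list was 3.36e-06, and its adjusted p was 0.375 with an estimated correlation. Its median of -0.50 was -0.81 without control replicates 2 and 3 and -1.42 with the marrow level as a covariate, settings chosen after the data were seen. The marrow markers were lower in the mutants too, but among the controls the array with the most marrow signal had the lowest mean of this list (9.79), and the array with the least had the highest (10.11).

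Among genes of terminal hypertrophy and mineralization the members went both ways. Mmp13, a collagenase, rose by 2.23 (SE 0.25, adjusted p = 0.00194), and Phospho1, a phosphatase that starts mineral formation in matrix vesicles, fell by 2.17 (SE 0.15, adjusted p = 0.000377). These were the only calls among 7 genes, against 5 when adjusted over the list alone, 3 higher and 2 lower, and the list was not called (adjusted p = 0.707). Of 7 resting zone genes, Grem1, a secreted antagonist of BMPs, rose by 1.70 and Spon1 by 1.58, and the same number passed when adjusted over the list alone. The list was called (adjusted p = 0.0397), with an adjusted p of 0.375 with an estimated correlation and of 0.119 without control replicate 3. Its median of 0.32 was 0.68 without control replicates 2 and 3 and -0.048 with the marrow level as a covariate. The calls of the list and of Grem1 also ended without mutant replicate 2 and without mutant replicate 3, with an adjusted p of up to 0.0595 for Grem1. Of 6 hedgehog response genes, Gli2 (0.71) and Smo (0.32) rose, 3 passed when adjusted over the list alone, 2 higher and 1 lower, and the list was not called (adjusted p = 0.814). Without mutant replicate 3 the adjusted p was 0.0684 for Gli2 and 0.177 for Smo. Gli1 and Ptch1, direct targets of hedgehog signalling, differed by -0.26 (adjusted p = 0.222) and -0.05 (adjusted p = 0.846). Hhip, another member of this list, was lower in every mutant array than in any control array, by 0.78, but was not called (adjusted p = 0.0569). Of 7 articular surface genes, Gdf5, a joint growth factor, rose by 1.43 (SE 0.12, adjusted p = 0.00066) and Abi3bp by 0.75, which lost its call without mutant replicate 3 (adjusted p = 0.0594) and without mutant replicate 2. Both also passed when adjusted over the list alone, and the list was not called (adjusted p = 0.305).

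Cell cycle transcripts were lower in the mutants. Of 19 G1/S genes, 12 fell, and 17 when adjusted over the list alone; of 19 G2/M genes, 17 fell, and 19 when adjusted over the list alone. Mki67, the proliferation marker Ki-67, fell from 10.22 ± 0.79 to 8.28 ± 0.08 (SD, n = 3 each), 3.83-fold (adjusted p = 0.0105). Ccna2, cyclin A2, fell by 1.36 (SE 0.24), and so did Nusap1 (-1.41) and Kif11 (-1.35), which act on the spindle. Among G1/S genes, Cdc6 (-1.97, SE 0.41), Mcm2 (-1.47, SE 0.39) and Mcm5 (-1.54), which license DNA replication, and Uhrf1 (-1.62) fell. The camera adjusted p was 2.57e-09 for G1/S and 2.12e-12 for G2/M, with adjusted p of 0.469 and 0.375 with an estimated correlation. Without mutant replicate 3 the adjusted p was 0.0776 for Cdc6, 0.135 for Mcm2, 0.057 for Uhrf1, 0.0513 for Mcm5 and 0.0536 for Nusap1. Among the controls, these lists and the marrow markers had their highest level on the same array. The G2/M mean was 8.06, 8.40 and 9.02 in control replicates 1, 2 and 3, and 7.35, 7.39 and 7.39 in the mutants. The list medians of -0.88 for G1/S and -1.10 for G2/M were -0.43 and -0.69 without control replicates 2 and 3. With the marrow level as a covariate they were 1.30 and 1.07, higher in the mutants, with camera adjusted p of 2.1e-07 and 7.63e-05. Of 7 CDK inhibitor and growth arrest genes, Cdkn1c, which encodes the inhibitor p57, fell by 1.64 (SE 0.18, adjusted p = 0.00174) and Gadd45b fell by 0.80, and 4 fell when adjusted over the list alone. This list was called lower (adjusted p = 0.00746), with an adjusted p of 0.295 with an estimated correlation. Its median of -0.47 was -0.27 without control replicate 3, -0.24 without control replicates 2 and 3, and -0.25 with the marrow level as a covariate.

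**Figure D2:**
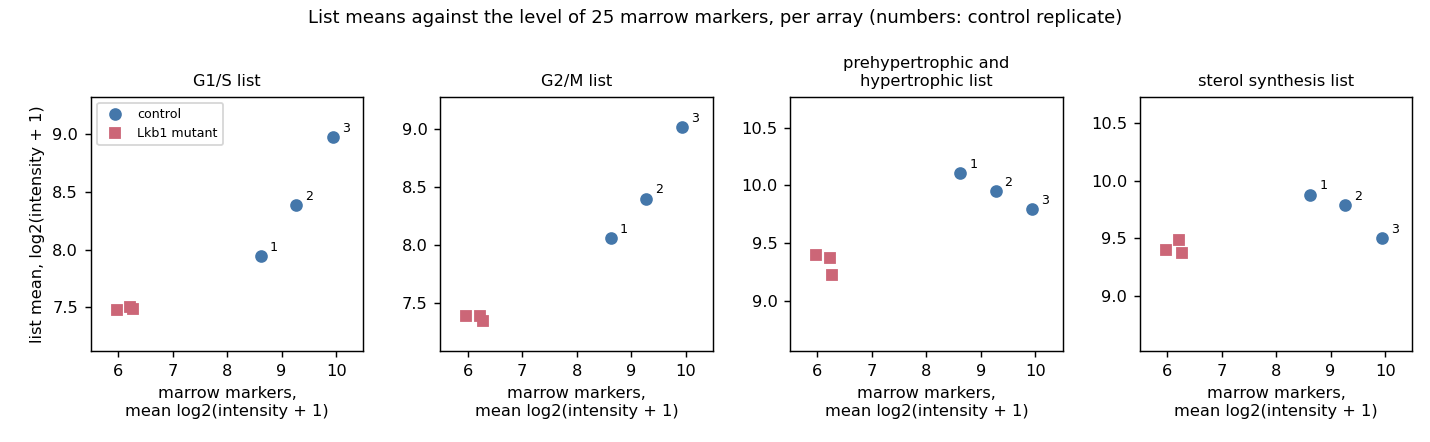
Mean log2(intensity + 1) of 4 gene lists per array (vertical axes, each spanning the same range) against the mean log2(intensity + 1) of 25 marrow markers (horizontal axis); circles are controls with their replicate number, and squares are Lkb1 mutants. Control replicate 3, at a marrow level of 9.94, has the highest G1/S and G2/M means and the lowest prehypertrophic and sterol means of the controls, and the mutants lie at marrow levels between 5.98 and 6.27.

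Markers of fibrous connective tissue, endothelium and most macrophage genes were higher in the mutants. Of 10 fibrous tissue and tendon genes, 6 rose and none fell, and 7 rose when adjusted over the list alone. Tnmd, the tendon gene tenomodulin, rose by 2.38 (SE 0.23, adjusted p = 0.00121), Col3a1 by 1.73 (SE 0.19) and Lum by 1.00, the last with an adjusted p of 0.0792 without mutant replicate 3. The list's camera adjusted p was 1.32e-05, with 0.332 as the adjusted p with an estimated correlation. Its median of 0.80 was -0.0079 with the marrow level as a covariate. Of 10 endothelial genes, 8 rose, and 10 when adjusted over the list alone, with a camera adjusted p of 2.42e-07 and an adjusted p of 0.295 with an estimated correlation. Emcn, endomucin, rose by 1.47 (SE 0.11) and Cdh5, VE-cadherin, by 1.30 (SE 0.14), followed by Esam (1.00) and Kdr (0.90), and Kdr had an adjusted p of 0.0615 without mutant replicate 3. Of 9 macrophage genes, 7 rose and 2 fell, with the same numbers when adjusted over the list alone. Mrc1 and C1qc rose by 0.98 and 0.97, while Cd14 and Lyz2, which monocytes and neutrophils also express, fell (-1.22 and -0.98). Without control replicate 2 the adjusted p was 0.0877 for Mrc1 and 0.0555 for C1qc, and it reached 0.148 for Cd14 without mutant replicate 3 and 0.143 for Lyz2 without mutant replicate 2. The macrophage list was called higher (adjusted p = 0.0146), with an adjusted p of 0.504 with an estimated correlation and 0.112 with the marrow level as a covariate. Its median of 0.73 was 0.63 without control replicates 2 and 3 and 0.95 with that covariate.

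Of 11 genes for matrix proteases and their inhibitors, 6 rose, and 7 passed when adjusted over the list alone, 6 higher and 1 lower. Adamts4, an aggrecan-cleaving protease, rose by 1.72 (SE 0.18, adjusted p = 0.00136), Mmp14, a membrane-bound collagenase, by 1.52 (SE 0.16), Timp2 by 0.83 and Mmp2 by 0.73, with an adjusted p of 0.0796 for Mmp2 without mutant replicate 3. The list was called higher (adjusted p = 0.00144), with an adjusted p of 0.484 with an estimated correlation. Its median of 0.44 was 0.35 without control replicates 2 and 3. With the marrow level as a covariate its median was -0.50, and camera called the list lower (adjusted p = 0.0115). In the same samples 6 of 10 fibrous tissue and 8 of 10 endothelial genes rose. Their lists were not called by camera with an estimated correlation (adjusted p = 0.332 and 0.295). Of 8 osteoblast and osteocyte genes, Col1a1 rose by 1.91 (SE 0.15, adjusted p = 0.00052) and Col1a2 by 0.77, while Smpd3 fell by 1.26 (SE 0.16) and Phex fell by 0.80, with an adjusted p of 0.0895 for Phex without mutant replicate 3. Adjusted over the list alone, 3 rose and 2 fell, and the list was not called (adjusted p = 0.339). Of 11 osteoclast genes, Atp6v0d2, a proton pump subunit, rose by 1.54 (SE 0.13) and Ctsk, cathepsin K, by 1.30 (SE 0.15), and Calcr fell by 0.33, a call that ended in each fit without 1 array (adjusted p of up to 0.196). Adjusted over the list alone, 2 rose and 3 fell, and the list was not called (adjusted p = 0.295). Of 10 skeletal muscle genes, Myl1 (0.86) and Actn3 (0.44) rose, and 3 when adjusted over the list alone (list adjusted p = 0.0535). Myl1 exceeded the background in no array, and of the 10 genes 3 exceeded it in all controls and 4 in all mutants. Of 7 adipocyte genes, Fabp4 (1.09) and Lpl (0.77) rose, likewise 2 when adjusted over the list alone (list adjusted p = 0.143). In all controls 1 adipocyte gene exceeded the background, and in all mutants 4 did. The adjusted p of Actn3 reached 0.132 without mutant replicate 2, and those of Fabp4 and Lpl were 0.0516 and 0.0706 without mutant replicate 3.

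**Figure D3:**
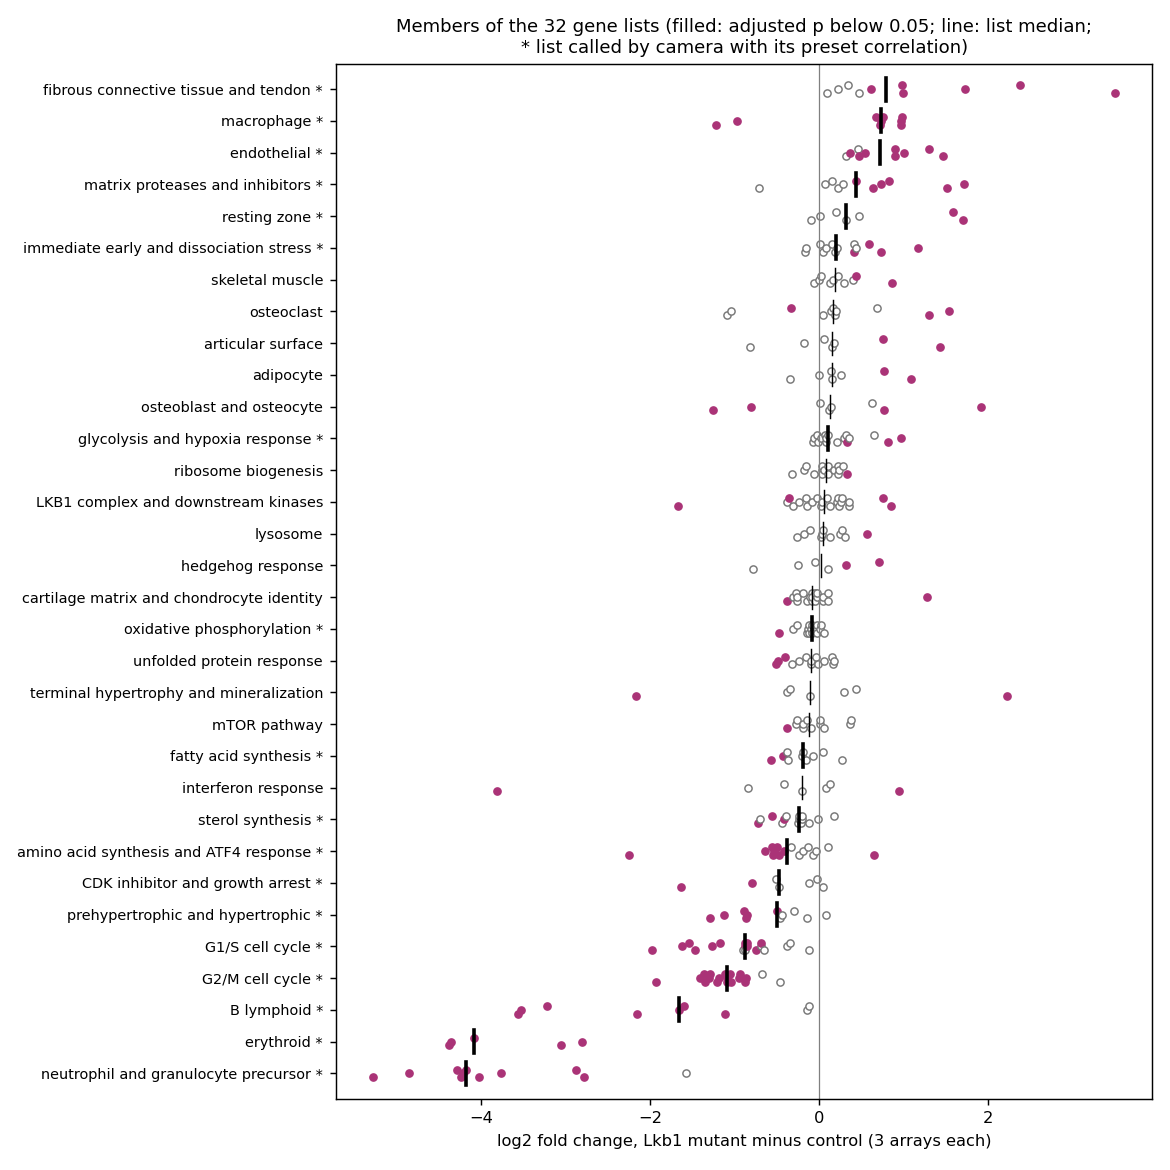
Log2 fold change, Lkb1 mutant minus control with 3 arrays each (horizontal axis), of every measured member of the 32 gene lists (vertical axis, sorted by median); filled points passed an adjusted p of 0.05 over all genes, vertical lines are list medians, and an asterisk marks a list called by camera with its preset correlation. The medians run from -4.18 for the neutrophil list to 0.80 for the fibrous tissue and tendon list, and 18 lists carry an asterisk.

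Several genes of lipid and amino acid synthesis were lower in the mutants. Of 15 sterol synthesis genes, 3 fell (Dhcr7 -0.73, Fdps -0.56 and Mvd -0.41), and 5 when adjusted over the list alone. The list was called (adjusted p = 0.000233), with an adjusted p of 0.484 with an estimated correlation. Of 10 fatty acid synthesis genes, the desaturases Fads2 (-0.57) and Scd2 (-0.43) fell, and 4 genes when adjusted over the list alone. The list was called (adjusted p = 0.0172), with an adjusted p of 0.565 with an estimated correlation and 0.175 without control replicate 1, where its median was -0.12. Without mutant replicate 3 all 5 of these gene calls ended, with adjusted p of 0.0707 for Dhcr7, 0.0632 for Fdps, 0.183 for Mvd, 0.0702 for Fads2 and 0.146 for Scd2. The medians of the sterol and fatty acid lists, -0.24 and -0.20, were -0.33 and -0.35 without control replicates 2 and 3, and -0.98 (adjusted p = 7.44e-09) and -1.02 (adjusted p = 1.89e-06) with the marrow level as a covariate. Of 16 genes of amino acid synthesis and the ATF4 response, 8 fell and 1 rose, and 10 and 1 when adjusted over the list alone. Slc7a11, a subunit of the cystine transporter, fell by 2.26 (SE 0.23, adjusted p = 0.00126), Chac1 fell by 0.64 (SE 0.11) and Asns, asparagine synthetase, fell by 0.56 (SE 0.09), while Ddit4, an inhibitor of mTORC1, rose by 0.65 (SE 0.10). Among the controls Slc7a11 was highest on the array with the most marrow signal (9.43), and Chac1, Asns and Ddit4 were highest on the array with the least. The camera adjusted p was 2.9e-05, and the adjusted p was 0.295 with an estimated correlation.

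Of 17 genes of glycolysis and the hypoxia response, Egln3, Car9 and Pfkl rose, by 0.97, 0.82 and 0.34, and 5 when adjusted over the list alone. Egln3 and Car9 are induced by hypoxia, and Pfkl is a glycolytic enzyme, whereas Ldha and Pgk1 differed by 0.02 and -0.03 (adjusted p = 0.9 and 0.886). The list's adjusted p was 0.0352, against an adjusted p of 0.484 with an estimated correlation; its median of 0.11 was 0.20 without control replicate 1 (adjusted p = 0.00486), 0.01 without control replicates 2 and 3, and -0.32 with the marrow level as a covariate. Its call ended without control replicates 2 and 3 taken out singly and without mutant replicate 3 (adjusted p of up to 0.121). The highest adjusted p without 1 array was 0.0873 for Egln3, 0.108 for Car9 and 0.124 for Pfkl. Of 14 immediate early and dissociation stress genes, Nr4a1 rose by 1.17 (SE 0.09, adjusted p = 0.000579), Fos by 0.74 (SE 0.10), Ier3 by 0.59 and Btg2 by 0.42, and 5 genes when adjusted over the list alone. This list was called higher (adjusted p = 0.00422), with an adjusted p of 0.295 with an estimated correlation and 0.592 with the marrow level as a covariate. Its median of 0.20 was 0.18 with that covariate. Ier3 and Btg2 lost their calls without some arrays, with adjusted p of up to 0.0782 without mutant replicate 2 for Ier3 and 0.0702 without mutant replicate 3 for Btg2. Of 16 oxidative phosphorylation genes, Cox5a fell by 0.48, with an adjusted p of 0.118 without mutant replicate 3, and 0 genes passed when adjusted over the list alone. The list was called lower (adjusted p = 0.0465), with an adjusted p of 0.484 with an estimated correlation, and it lost the call without control replicates 1 or 3 and without mutant replicates 2 or 3 (adjusted p of up to 0.119). Its median of -0.09 was -0.045 without control replicate 3 and 0.12 with the marrow level as a covariate.

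Of the 22 partners and downstream kinases of LKB1, 2 rose and 2 fell, and 9 passed when adjusted over the list alone, 6 higher and 3 lower. Sik1 and Sik2, salt-inducible kinases, rose by 0.85 (SE 0.15, adjusted p = 0.0107) and 0.76 (SE 0.11, adjusted p = 0.0055). Stradb, a pseudokinase that binds LKB1, fell by 1.67 (SE 0.37, adjusted p = 0.0246), and among the controls it too was highest on the array with the most marrow signal. Mark2 fell by 0.36 in the probe set used and differed by -0.18 in a second probe set. Prkaa1 and Prkaa2, the catalytic subunits of AMPK, differed by -0.14 and 0.23 (adjusted p = 0.392 and 0.252). Without mutant replicate 3 the adjusted p of Sik1 was 0.0534, and the calls of Stradb and Mark2 ended without several single arrays, with adjusted p of up to 0.0839 and 0.145. The list was not called (adjusted p = 0.586). Of 12 mTOR pathway genes, Eif4ebp1 fell by 0.38 (adjusted p = 0.0421, and up to 0.155 without 1 array), 0 passed when adjusted over the list alone, and the list was not called (adjusted p = 0.242). Of 14 unfolded protein response genes, Sdf2l1 (-0.51), Hyou1 (-0.48) and Manf (-0.41) fell, each lost its call without some array (adjusted p of up to 0.084, 0.077 and 0.0955), and 4 fell when adjusted over the list alone (list adjusted p = 0.0621). Of 11 lysosome genes, Hexa rose by 0.57 (SE 0.09), likewise 1 when adjusted over the list alone (list adjusted p = 0.327). Of 16 ribosome biogenesis genes, Gnl3 rose by 0.33, with an adjusted p of up to 0.18 without 1 array, and 0 passed when adjusted over the list alone (list adjusted p = 0.526). Of 7 interferon response genes, Rsad2 fell by 3.81 (SE 0.44, adjusted p = 0.00214) and Ifit3 rose by 0.95 (SE 0.12, adjusted p = 0.00267), the same number passed when adjusted over the list alone, and the list was not called (adjusted p = 0.366). Rsad2 was at 8.94, 9.61 and 10.96 in control replicates 1, 2 and 3, rising with the marrow markers. Over the 7 genes control replicate 3 exceeded control replicate 1 by a median of 1.41 (SD 0.73 over the members).

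In all, camera called 18 of 32 lists at an adjusted p of 0.05, 7 higher and 11 lower in the mutants. With an estimated correlation it called 0, with a lowest adjusted p of 0.295 and 5 lists at an unadjusted p below 0.05, and fry, which asks whether a list's genes move on balance one way, called 15. Lists not called with all arrays were called in some other fits: skeletal muscle higher without control replicate 2 and without mutant replicates 1 or 3 (lowest adjusted p = 0.0235), and the unfolded protein response lower without control replicate 3 and without mutant replicates 1 or 3 (lowest adjusted p = 0.0417). Without control replicates 2 and 3 the medians of the adipocyte and articular surface lists were 0.38 and 0.32, against 0.15 and 0.15 with all arrays. With the marrow level as a covariate, the terminal hypertrophy and hedgehog lists were called lower (medians -0.48 and -0.97), and the osteoclast, adipocyte and interferon lists higher (1.08, 0.96 and 1.66). Of the 18 lists, camera with the marrow level as a covariate called 5 the same way (prehypertrophic and hypertrophic, endothelial, sterol synthesis, fatty acid synthesis, and amino acid synthesis and ATF4 response), 3 the other way (G1/S, G2/M, and matrix proteases and inhibitors) and 10 not at all. The level of marrow markers separates the groups completely, so a difference between genotypes and a difference in marrow content are tied together in these samples.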

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

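The tests of the cell cycle lists, of the prehypertrophic and hypertrophic list and of the order of genes among the controls were chosen only after the results were seen. Outside the main measurement, which used probe sets of 1 gene, 116 probe sets that the annotation does not list and 25 probe sets of several genes drew attention as signal in data that the comparison did not use, higher in the mutants at a limma adjusted p of 0.05, out of 6702 and 1369 tested; 187 and 58 were lower. They carry no single gene name here, and no explanation was tested for them. Groups of 3 arrays were not searched for single distant samples.

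The 2496 genes called between mutant and control were weighed against the split of the arrays, the sex of the mice and a different share of bone marrow cells; limma called 2496 genes in the real split and 0 in the highest of the others (121 to 856 at an unadjusted p under 0.05), 1 of 10 splits gave as many as the real one, and 10 are too few for a share under 0.05. Control replicate 2 alone had Y-linked signal (Uty at 7.12, the other arrays at most 5.12). Its Xist level was low at 5.47, against 10.62 to 10.89 on the others. The median Y-linked difference was -0.80, between the bounds of 0.5 and 1 set for it, so that test stays undecided. The difference was -0.13 without that array, where 1329 genes were called, 1296 of them among the 2496. This argues against sex as the cause of those 1296 calls, and the other calls stay open. A lower marrow share could account for part of the calls: 59.0% of the genes called lower had the order of the marrow markers among the controls and 43.8% of those called higher the opposite order, against 29.5% and 21.4% of all genes tested and 16.7% by chance. The macrophage median of 0.73 ran against the erythroid median of -4.09, past the bound of 0.2 written for arguing against marrow share as the whole cause, but it lies within its members' SD of 0.86; the demand that it exceed this SD was put into the test after the value was seen, and without it the test would have counted against that cause. Marrow share and genotype cannot be told apart for these genes as a whole, because the marrow level separates the groups completely.

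The lower cell cycle lists may reflect marrow cells, many of which divide, in the control samples rather than chondrocytes. Over the 38 members, control replicate 3 exceeded control replicate 1 by a median of 0.94 (SD 0.35), in the direction of their mean marrow intensity of 1556 and 683, against 98.4 to 189 in the mutants. A straight line through the 3 controls, of intensity against mean marrow intensity, was extended to the mutants' marrow level with a lower limit of 20. That marrow level lies outside the range of the controls, and the limit lies below the filter's cut-off intensity of 46.2. The measured mutant levels lay above the predicted ones by a median of 0.96 (SD 1.05), with 7 members at the limit. A member predicted below background is measured above its prediction in any case, so for such members the line could not have shown a further decrease. No decrease beyond the marrow prediction was seen over the 38 members. A change of division in the mutant chondrocytes themselves, in either direction, stays open.

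The lower prehypertrophic and hypertrophic list is not accounted for in the same way. Extended from the controls, the same line predicts higher levels than measured, with a median difference of -1.04 (SD 0.50 over the members) against -0.50 before. That SD is a spread between genes and holds no error of the line. The line rests on 3 controls and reaches outside their marrow range. The list mean was 10.11, 9.95 and 9.79 in control replicates 1, 2 and 3, so it fell as the marrow level rose. Within these limits, both argue against marrow cells in the controls as the source of the decrease. Dilution of chondrocytes by other cells in the mutants would lower all chondrocyte genes, but 0 of 20 cartilage genes fell by as much as the list's median, the lowest was Sox6 at -0.38, and the count was also 0 without each array and without control replicates 2 and 3, which argues against dilution as the whole cause; with the marrow covariate the lowest, Matn1 at -1.41, was close to the list's median of -1.42. The cartilage list was itself called lower without control replicate 3 and with the covariate (medians of -0.13 and -0.53). Its median was -0.16 without control replicates 2 and 3, and its genes differed from the same line's prediction by a median of -0.27 (SD 0.23). Bright members such as Col2a1, at 12.35 in the controls, may understate a dilution if the arrays saturate, which was not tested. Dilution therefore stays open as a part. A hypothesis that remains is a smaller share of prehypertrophic and hypertrophic cells, or a lower level in them, in the mutant samples, whether from the genotype or from how the tissue was dissected, which no label or value settles.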

How the results depend on the processing

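The fits without control replicates 2 and 3 and with the marrow level as a covariate were chosen only after the results were seen; the others were planned. Under the planned settings 0 called lists and 0 named genes changed direction, and 65 of 109 named genes kept their call without each array in turn. In the planned settings that neither leave out an array nor change the list test, 3 of the 18 called lists lost the call: oxidative phosphorylation with the filter at the median, array weights, quantile normalisation and the replicate block, resting zone with the filter at the median and array weights, and glycolysis with the filter at the median. In these settings 16 named genes lost the call (Sox6, Smo, Calcr, Cd14, Lyz2, Actn3, Mcm2, Mvd, Scd2, Car9, Pfkl, Manf, Cox5a, Gnl3, Mark2 and Eif4ebp1), up to 14 in a setting (the replicate block), and the filter at the median left out 6 named genes. Without 1 array the calls ranged from 936 to 3282, those higher from 512 to 1642 and those lower from 424 to 1640, with 1329 without control replicate 2 and 1198, 1185 and 936 without mutant replicates 1, 2 and 3. The highest count was without control replicate 1, and the cause was not tested. Array weights, whose fit did not converge and gave control replicate 2 a weight of 10.1, gave 8006 calls, 4406 higher and 3600 lower. A size of at least 1 left 723. The share of higher calls was 53.5%, and 46.5% with median centring. Camera with an estimated correlation called 0 lists, with 5 at an unadjusted p under 0.05, and fry called 15, of which 12 are among the 18. Deviations of same-numbered arrays from their group means correlated at r = 0.08, 0.07 and -0.06. In these deviations the best-matching mutant array had the same number for control replicates 1 and 2, but not for control replicate 3. With 3 arrays per group these values cannot tell whether the numbers pair the samples. With a replicate block 2031 genes were called. Without control replicates 2 and 3, 1779 genes were called, 885 of them higher; the lone control is assumed to vary like the mutants. Under the planned settings Stk11 lay between -1.90 and -1.41.

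With the marrow level as a covariate 2 genes were called, 1 higher and 1 lower, and 28 named genes and Stk11 changed sign. So did the medians of 12 of the 32 lists, 9 of them among the 18 called lists. Of these 18, camera called 5 the same way, 3 the other way (G1/S, G2/M, and matrix proteases and inhibitors) and 10 not at all. The covariate correlates with genotype at r = -0.97, and the median SE over all genes rose from 0.115 to 0.38; Stk11 went from -1.67 (SE 0.22) to 0.48 (SE 0.44). Calls end through this wider error and through the shift of the estimates, and this fit does not tell marrow content from genotype. The log2 differences turned to -0.78 for Postn, 0.44 for Slc4a1, 2.13 for Rhag, 1.47 for Car2, 2.47 for Car1, -1.41 for Matn1, 0.0014 for Sox6, -0.048 for Spon1, -0.089 for Smo, 3.96 for Klf1, 0.39 for Vpreb3, 1.78 for Cd14, -0.22 for Mrc1, 1.18 for Lyz2, -0.86 for Lum, 2.42 for Cdc6, 1.46 for Uhrf1, 1.30 for Mcm5, 2.60 for Mcm2, 1.54 for Mki67, 1.23 for Nusap1, 1.02 for Ccna2, 0.74 for Kif11, -0.061 for Gnl3, 2.15 for Stradb, -0.030 for Timp2, -0.60 for Mmp2 and 0.81 for Rsad2. Among the called lists the medians turned to -0.048 for resting zone, 2.13 for erythroid, 0.20 for B lymphoid (whose camera direction stayed lower), -0.0079 for fibrous connective tissue and tendon, 1.30 for G1/S, 1.07 for G2/M, -0.32 for glycolysis and hypoxia response, 0.12 for oxidative phosphorylation and -0.50 for matrix proteases and inhibitors; among the others, to -0.97 for hedgehog response, -0.23 for ribosome biogenesis and 1.66 for interferon response.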

Other observations

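The gene groups, the contrasts and the line for Stk11 in this part were chosen only after the results were seen. In all, 8 groups were tried, and they carry counts and no group test. The fibrous tissue and endothelial lists had medians of 0.80 and 0.72 in the same samples. A change in the mixture of cells was not told apart from a change within cells for these groups. Genes of smooth muscle and pericytes were mostly higher in the mutants. Of 12 measured, 8 rose and 1 fell, with Acta2, smooth muscle actin, 4.92-fold higher (limma adjusted p = 0.000239), Rgs5 4.60-fold and Pdgfrb 2.37-fold, while Cspg4 fell by 0.34. The counts of risen genes here and in the Wnt group include Abcc9 and Wnt5a, respectively, which exceeded the background in no array. Of 16 genes of FGF and IGF signalling, 10 rose, among them Igfbp3 (from background in 2 of 3 controls), Igfbp4 (3.24-fold), Igf1 (2.56-fold), Fgfr2 (2.54-fold) and Igf2 (2.36-fold). Of 19 genes of Wnt signalling, 9 rose and 1 fell; of the secreted modulators, Dkk3 rose 3.08-fold and Sfrp2 rose from background in 2 of 3 controls, Wnt5b fell by 0.64, and Axin2, a target of the pathway, differed by -0.07 (adjusted p = 0.698) and was at background in 1 mutant array. Of 19 genes of BMP and TGF-beta signalling, 7 rose and 1 fell, with Id1, a target of BMP signalling, 2.28-fold higher and Smad7 at -0.40. Of 13 genes of the embryonic limb and joint, 5 rose, with Prrx1, a transcription factor of limb mesenchyme, 2.96-fold higher, while Prrx2 and Twist1 rose from background in 2 and 1 of 3 controls. Of 16 further collagen chains, 8 rose, such as Col5a2 (2.39-fold) and Col5a1 (2.28-fold), while Col6a3 differed by -0.04. Of 5 platelet genes, Ppbp (-3.72) and Gp9 (-2.54) fell to background, in the direction of the other marrow lineages. Of 13 genes of phosphate and mineral transport, 2 rose and 2 fell, with Slc8a3 2.60-fold lower and Mgp, an inhibitor of mineralization, 1.27-fold higher.

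Contrasts that share no array ran against each other across the 17020 genes. The difference of control replicate 3 from control replicate 1 correlated at r = -0.49 with the difference of the mutants from control replicate 2. The other pairings gave -0.39 for control replicate 2 from 1 and -0.24 for control replicate 3 from 2. Genes are not independent replicates, so no p is given. The Stk11 level that the line through the controls gives at the mutants' marrow level was exceeded by the measured level, by 0.39 on the log2 scale, and Stk11 was 0.98 higher in control replicate 3 than in control replicate 1.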
